A study of Caenorhabditis elegans with 6 samples.

How the data were processed

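The values come from 6 Affymetrix C. elegans arrays, 3 of worms exposed to albendazole (ABZ) and 3 of worms exposed to the solvent dimethyl sulfoxide (DMSO) alone. Each array was hybridised with material from a single sample of 1 µg of total RNA from whole worms, and no pooling is stated. Per the labels, the deposited values were made with RMA, and limma is also named, without a version or an order of steps for either. The deposited values were read as log2 signal per probe set. That scale was inferred from their range of 4.887 to 14.89 and is not stated; no raw scans were used here. The medians of the arrays lie within 0.071 of each other on the log2 scale, and probe sets had not been centred. The table holds no detection calls, so whether a probe set lies above background could not be read from it, and the number of arrays limits the precision of every value.

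All 22625 probe sets of the table were read. The 77 Affymetrix control probe sets were left out of the tests and used only to compare arrays, which left 22548 probe sets. Gene names came from the platform's annotation, in which 20766 of these probe sets list 1 gene, 887 list several and 895 list none. The symbols of 20701 probe sets were looked up again through their gene number in a RefSeq gene table of the WBcel235 assembly; 0 symbols changed and 65 gene numbers were not found. A gene is represented by the probe set with the highest mean signal among those that list this gene alone, which gave 17118 genes. Probe sets that list several genes were tested but not used to name genes. No genome positions are given, since the build behind the annotation is not stated.

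Both groups were compared with limma version 3.58.1 in R version 4.3.3, by a linear model with group as its only term and the moderated t-statistic of eBayes with default settings, two-sided. P values were adjusted by Benjamini-Hochberg over the 22548 probe sets, and a probe set was called at an adjusted p under 0.05. Each log2 fold change is albendazole minus DMSO, and SE is its standard error from this model. A gene list was tested with limma's camera with a preset inter-gene correlation of 0.01, which compares the list with all other genes, and adjusted p values were taken over 34 lists. These lists were fixed by gene name, cover drug metabolism, stress responses, the cytoskeleton and cell division, reproduction, tissues, immunity, metabolism and protein turnover, and are each described with their result. They overlap: the cyp-35 subfamily is part of the cytochrome P450 list, for example. The members of each list were also counted with their p values adjusted over the list alone.

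The comparison, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule names up to 15 called genes in each direction and up to 4 called genes in each list. Where fewer than 10 genes pass, it takes the 10 smallest p values in each direction and says that they do not pass. It always names ben-1, tbb-1, tbb-2, mec-7, tba-1, tba-2, vit-2 and every measured cyp-35 gene. Genes that passed adjusted over their list alone are named too, and ugt-16 is named on this ground only. Any other gene outside this rule is named as such. Fisher's exact test of gene-name classes was planned on called genes and could not be run with 0 genes called. Classes with at least 8 measured genes were tested with camera instead, which was decided after the values had been seen.

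The alternatives chosen in advance were to leave out the dimmest part of the probe sets (1 in 3), shift all arrays to 1 median, quantile normalization, the replicate number as a block, eBayes with an intensity trend and robust settings, array weights, each array left out in turn, an adjusted p under 0.01, a change of at least 2-fold, a count of genes in place of probe sets, the mean of each gene's probe sets, camera with an estimated correlation, and fry. Added after the values had been seen were cyclic loess normalization, array weights by the gene-by-gene method, DMSO replicate 1 left out with the intensity trend and robust settings, list tests after the trend of the statistics with signal was removed (loess, span 0.3), the same without DMSO replicate 1, camera with an estimated correlation with arrays left out, and replicate 1 of both groups left out. The default fit of the array weights stopped before it converged, which is why the gene-by-gene method was added. The labels state no pairing of the cultures, and none was used in the main comparison.

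The steps were tested on simulated data with the same layout and 22548 probe sets, in which 200 probe sets were changed. With all 6 arrays, 38.8% of the 2-fold, 82.1% of the 4-fold and 87.9% of the 8-fold changes were called, with 13 false calls. With DMSO replicate 1 left out, 86.6%, 97% and 100% were called, with 15 false calls. In a simulated set of 17118 genes, camera called 1 raised list of 1 and 0 of 33 unchanged lists. The noise was drawn independently for each probe set, without correlated genes and without an array that stands apart. These rates therefore do not carry over to the real arrays.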

Results

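Transcript levels were measured on Affymetrix arrays in whole C. elegans of strain CB3474, which carries the allele e1880 of ben-1. This gene encodes a β-tubulin whose loss makes the worm resistant to benzimidazole drugs such as albendazole. The worms were grown in liquid culture at 20 °C for 70 h from the first larval stage, and the exposure lasted 4 h. In the 3 albendazole samples the medium held 300 µg/ml of the drug in 1.5% DMSO by volume, and in the 3 control samples 1.5% DMSO alone. The samples are biological replicates, numbered 1 to 3 in each group. All 6 arrays carry the same mutation, so worms with and without it could not be compared.

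DMSO replicate 1 stood apart from the other 5 arrays. Its log2 values had an SD of 1.73 across probe sets, against 1.98 to 2.017 on the others, and its correlation across probe sets with each of them lay between 0.934 and 0.943. The correlations among the other 5 arrays reached from 0.988 to 0.996; probe sets are not independent replicates. In the dimmest of 5 equal bins of probe sets its values lay above the mean of the others by a median of 0.27, and in the brightest bin the median difference was -0.6. Gene groups that passed are given also without this array.

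**Figure D1:**
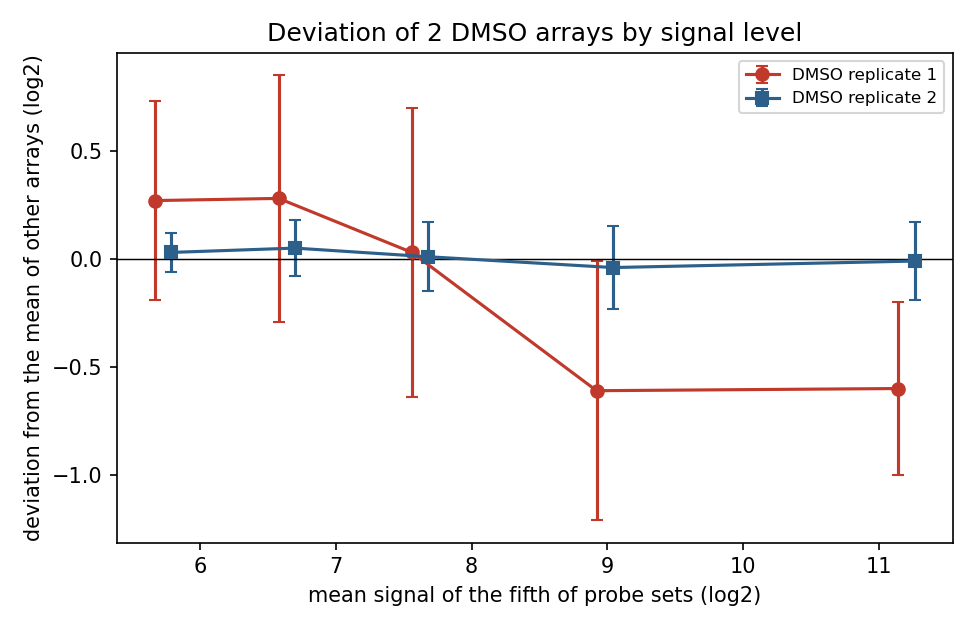
Median deviation of DMSO replicate 1 from the mean of the other 5 arrays, and of DMSO replicate 2 from the mean of DMSO replicate 3 and the 3 albendazole arrays (log2, vertical axis), in 5 bins of mean signal (log2, horizontal axis), with bars of 1 SD across the probe sets of a bin. DMSO replicate 1 runs from 0.27 in the dimmest bin to -0.6 in the brightest, and DMSO replicate 2 stays between -0.04 and 0.05.

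The comparison of albendazole with DMSO asks which transcripts differ after a short exposure to the drug in worms with the ben-1 mutation. No gene passed over all probe sets, and 7 genes of drug metabolism passed only when p values were adjusted over the list alone. The cytochrome P450 gene cyp-35C1 (NCBI gene 179885) had a log2 signal of 12.92 ± 0.58 with albendazole and 9.64 ± 0.20 with DMSO (SD, n = 3 each), a 9.67-fold higher signal (log2 3.27, SE 0.30). Its relative cyp-35A5 (gene 178802) stood at 10.75 ± 1.13 against 7.45 ± 0.27, 9.81-fold higher (log2 3.29, and 2.64 without ABZ replicate 2), and cyp-35A2 (gene 182177) at 11.32 ± 0.60 against 9.03 ± 0.91, 4.88-fold higher. The glutathione S-transferase gene gst-5 (gene 187537) stood at 12.38 ± 0.37 against 10.60 ± 0.29, 3.43-fold higher. Among the UDP-glycosyltransferases, which couple sugars to foreign compounds, ugt-16 was 3.19-fold and ugt-5 1.94-fold higher, and ugt-53 was lower, at 6.82 ± 0.17 against 7.63 ± 0.23. In each of these 7 genes all 3 albendazole values lay beyond all 3 DMSO values. Adjusted over the list alone, which does not correct for the number of lists, 6 were higher and 1 lower: cyp-35C1 at 3e-04, cyp-35A5 at 0.00434 and cyp-35A2 at 0.0141 in the cyp-35 list, gst-5 at 0.0118 and each ugt gene at 0.0473. The calls of gst-5 and of the ugt genes did not hold without every array or under every scaling, as given with their lists.

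Over all 22548 probe sets, limma called 0 higher and 0 lower, with a smallest adjusted p of 0.651. At an unadjusted p under 0.05 there were 343 higher and 77 lower probe sets, together 420, where 1127.4 are expected by chance. The excess of higher ones was nearly gone without DMSO replicate 1, at 669 higher and 625 lower. With array weights there were 2095 higher and 2567 lower. Without any other single array the higher ones still outnumbered the lower ones. All 3 albendazole values lay above all 3 DMSO values on 1762 probe sets and below them on 2278, together 17.92% of those tested. The average over all splits of the arrays, 3 against 3, is 10%. Probe sets on the same arrays vary together, so a single split can lie away from this average without any effect of the drug. The count of 0 changed in 3 settings. With array weights, 25 probe sets passed as higher and 3 as lower. These weights were 0.0428, 10.4 and 0.61 for DMSO replicates 1, 2 and 3, so the DMSO side rested mostly on replicate 2. ABZ replicates 1, 2 and 3 had 0.979, 2.25 and 1.67. The gene-by-gene weights gave 5 higher and 0 lower. Without DMSO replicate 1 and with the intensity trend and robust settings, 2 passed as higher, and both measure K08D8.6. The count of 420 became 1294 without DMSO replicate 1, 830 without DMSO replicate 3, 105 without ABZ replicate 1, 241 without ABZ replicate 2 and 272 without ABZ replicate 3, and the count of called probe sets stayed at 0 each time.

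The 10 genes with the smallest p values among those higher with albendazole did not pass; they were 1.52- to 9.81-fold higher. Besides cyp-35C1, cyp-35A5, gst-5 and ugt-5 they were K08D8.6 (gene 178241), hpo-6, cld-9, K09C4.5, drd-50 and F35E12.9. K08D8.6 stood at 10.86 ± 0.20 against 9.52 ± 0.21 (SD, n = 3 each), 2.53-fold higher, and its other probe sets gave log2 fold changes of 1.62 and 1.16. The log2 fold change was 0.73 for hpo-6, 0.92 for cld-9, 0.93 for K09C4.5, 1.12 for drd-50 and 0.61 for F35E12.9. With array weights, 19 genes passed as higher, among them cyp-35C1, cyp-35A5, cyp-35A2, gst-5, K08D8.6, hpo-6, cld-9, K09C4.5, drd-50 and F35E12.9. The 2 genes that passed as lower, lys-3 and gst-29, were chosen after their values were seen. With gene-by-gene weights 3 genes passed as higher, cyp-35C1, K08D8.6 and the heme transport gene hrg-1, which was also chosen after its values were seen and had a log2 fold change of 0.84 with the default weights.

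The 10 genes with the smallest p values among those lower did not pass either, and they were 1.23- to 1.76-fold lower. The log2 fold change was -0.82 for ugt-53, -0.54 for F53F1.6, -0.46 for F38B6.4 and -0.45 for nprt-1, which encodes a nicotinate phosphoribosyltransferase. It was -0.44 for F56C3.9, -0.43 for K12D12.5, -0.42 for scl-5, -0.33 for F39G3.4 and -0.32 for sru-46. The sex-determination gene tra-2 had -0.30, while its dimmer second probe set had 0.01; that of nprt-1 had -0.15. In each of these 20 genes, higher or lower, all 3 albendazole values lay beyond all 3 DMSO values. Leaving out DMSO replicate 1 could therefore not change their sign.

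**Figure D2:**
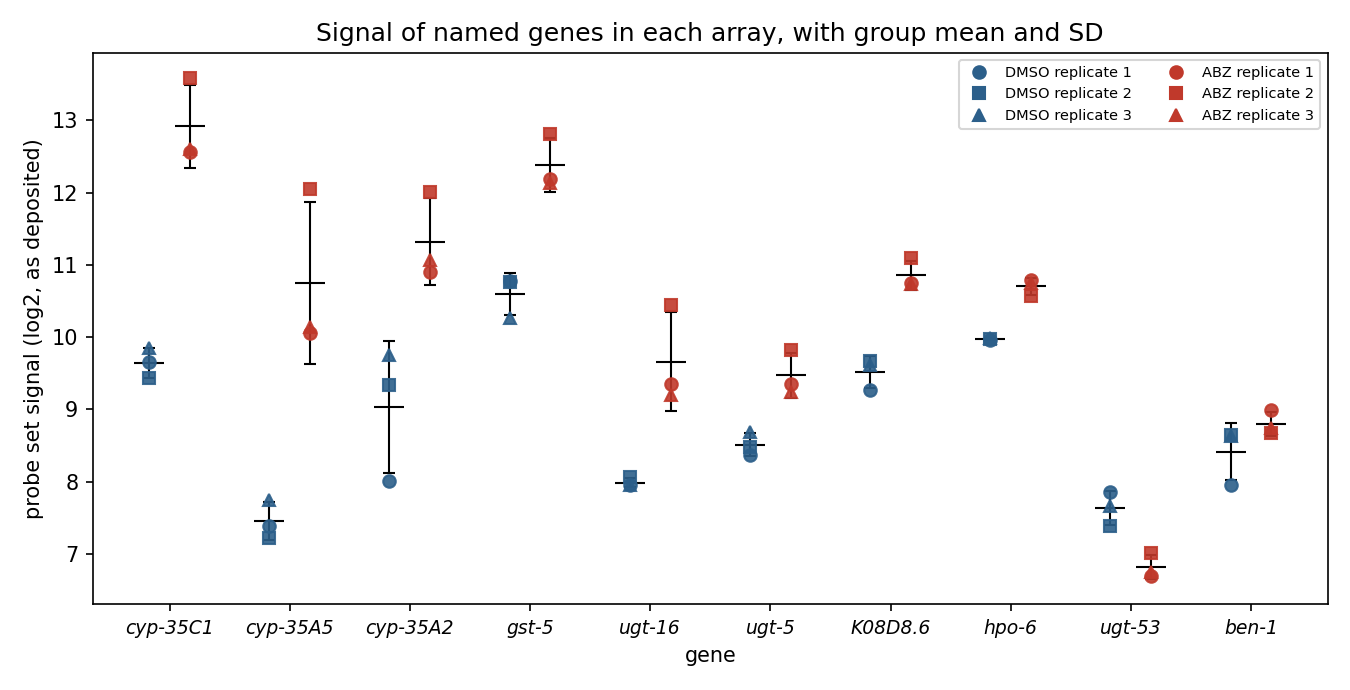
Log2 signal (vertical axis) of cyp-35C1, cyp-35A5, cyp-35A2, gst-5, ugt-16, ugt-5, K08D8.6, hpo-6, ugt-53 and ben-1 on each of the 6 arrays (points), with the mean and SD of the 3 albendazole and the 3 DMSO samples. The albendazole points of cyp-35C1 and cyp-35A5 lie above their DMSO points, with means of 12.92 against 9.64 and 10.75 against 7.45.

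The genes of the drug's target family did not pass. The signal of ben-1 was 8.80 ± 0.17 with albendazole and 8.41 ± 0.40 with DMSO (SD, n = 3 each), a log2 fold change of 0.39 that became 0.16 without DMSO replicate 1. The log2 fold change was 0.11 for tbb-1, 0.15 for tbb-2, 0.04 for tba-1 and 0.10 for tba-2, and without DMSO replicate 1 it was -0.06, 0.00, -0.15 and -0.06. The touch-neuron β-tubulin gene mec-7 had 0.21 and the yolk protein gene vit-2 had 0.17, against 0.18 and 0.04 without DMSO replicate 1. The signs of tba-1, tbb-1, tba-2 and mec-7 changed in 7, 5, 3 and 2 of the other settings.

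Of the 10 measured genes of the cyp-35 subfamily, 8 had a positive fold change, and the subfamily shifted up with a median of 0.67 and a mean of 1.13 (adjusted p 0.000543; adjusted p = 0.794 with an estimated correlation). Besides the 3 members above, cyp-35B1 had a log2 fold change of 0.87, cyp-35A1 0.82, cyp-35D1 0.52, cyp-35A3 0.44, cyp-35B2 0.28, cyp-35A4 -0.13 and cyp-35B3 -0.37, and none of these passed. Among the 3 albendazole arrays, ABZ replicate 2 held the highest value of 9 of the 10 genes, and without it the median was 0.22 (adjusted p 0.00301). Without DMSO replicate 2 it was 0.46 (0.0262), without DMSO replicate 1 0.79 (4.99e-06), and with replicate 1 of both groups left out 1.16 (1.95e-10). The direction held under all 3 scalings. The members have similar sequences, and whether their probe sets tell them apart was not tested.

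Across the whole cytochrome P450 list of 73 genes, 31 had a positive fold change, and the list did not pass (adjusted p 0.625). Its median of -0.08 and the test lay on the lower side and its mean of 0.10 on the higher, and the test turned to the higher side under quantile and cyclic loess normalization and without ABZ replicate 1 (0.56) or DMSO replicate 1 (0.768). In this list cyp-35C1 (0.00219) and cyp-35A5 (0.0317) passed adjusted over the list alone, but cyp-35A5 was lost without ABZ replicate 1 (0.0558), ABZ replicate 3 (0.0672), DMSO replicate 1 (0.0596), DMSO replicate 2 (0.154) or DMSO replicate 3 (0.0759). The call of gst-5 was lost without ABZ replicate 1 (0.0502) and under quantile (0.113) and cyclic loess normalization (0.0935). All 3 ugt calls were lost without DMSO replicate 1 (0.106 each) or DMSO replicate 3 (0.131 each). The same held without DMSO replicate 2 (ugt-16 and ugt-5 0.177, ugt-53 0.108) or ABZ replicate 1 (ugt-16 and ugt-5 0.189, ugt-53 0.207). Without ABZ replicate 2, ugt-5 and ugt-53 were lost (0.0773 each) and ugt-16 was kept (0.0115). Without ABZ replicate 3, ugt-53 was lost (0.122), and ugt-16 and ugt-5 were kept (0.0488 each).

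Of 64 UDP-glycosyltransferase genes, 38 had a positive fold change, and the list shifted up with a median of 0.06 (adjusted p 0.0484; adjusted p = 0.794 with an estimated correlation), in the same direction under all 3 scalings. Members with larger values that did not pass were ugt-63 at 1.92, ugt-22 at 1.30, ugt-41 at 1.09 and ugt-13 at 0.87, chosen after their values were seen. The list no longer passed without DMSO replicate 1 (0.0521), DMSO replicate 2 (0.15), DMSO replicate 3 (0.121) or ABZ replicate 2 (0.16). The 45 glutathione S-transferases had a median of 0.04 and did not pass (0.202). Other phase I enzymes, 53 genes with a median of 0.16, shifted up (0.0152; adjusted p = 0.794 with an estimated correlation). They did not pass under quantile (median -0.01, 0.832) or cyclic loess normalization (median -0.03, 0.958), and not without DMSO replicate 1 (median -0.01, 0.499) or ABZ replicate 2 (0.268). In that list the dehydrogenase-family gene dhs-23, chosen after its values were seen, had a log2 fold change of 1.18 and did not pass. The 56 ABC transporters had a median of 0.02 (0.865). The 254 nuclear hormone receptors shifted down with a median of -0.08 (0.0208; adjusted p = 0.794 with an estimated correlation), a direction that turned under quantile and cyclic loess normalization and a call that was lost without DMSO replicate 1 (0.768) or ABZ replicate 1 (0.105).

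Genes of the unfolded protein response of the endoplasmic reticulum shifted up: 25 of 32 had a positive fold change and the median was 0.30 (adjusted p 0.000504; adjusted p = 0.794 with an estimated correlation). The direction held under all 3 scalings, and without DMSO replicate 1 the median was 0.13 (4.99e-06). The chaperone gene hsp-3 had a log2 fold change of 0.43, and the protein disulfide isomerase genes pdi-6, pdi-2 and pdi-3 had 0.35, 0.32 and 0.28. These members were chosen after their values were seen, and none passed. The other stress lists did not pass: 37 oxidative stress genes had a median of 0.12 (adjusted p 0.184), 21 heat shock genes 0.10 (0.211), 12 genes of the mitochondrial unfolded protein response 0.21 (0.118) and 11 hypoxia response genes 0.15 (0.117). The hypoxia list passed without ABZ replicate 3 (0.0366) and without DMSO replicate 2 (0.0262). The medians of these 4 lists lay between -0.02 and 0.01 without DMSO replicate 1.

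Neuron genes shifted up, with 45 of 56 positive and a median of 0.17 (adjusted p 0.000504; adjusted p = 0.794 with an estimated correlation), in the same direction under all 3 scalings. Their median was 0.08 without DMSO replicate 1 (2.02e-05). The neuropeptide gene flp-8 had a log2 fold change of 0.85 and unc-18, which acts in synaptic release, 0.73; they were chosen after their values were seen and did not pass. Muscle genes shifted up with 30 of 32 positive and a median of 0.14 (0.000539; adjusted p = 0.794 with an estimated correlation). They did not pass under quantile (median 0.01, 0.832) or cyclic loess normalization (median 0.01, 0.758). Their median was 0.04 without DMSO replicate 1 (0.0113), and with replicate 1 of both groups left out it was 0.00 and the list did not pass (0.392). The 39 intestine genes had a median of 0.08 (0.0942) and passed without ABZ replicate 3 (0.00491) and without DMSO replicate 2 (0.0225).

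Several lists of bright genes passed with all 6 arrays and not without DMSO replicate 1, each with an adjusted p = 0.794 with an estimated correlation. Tubulins and tubulin folding genes (36) shifted up with a median of 0.21 (adjusted p 0.00127) and had 0.05 (0.082) without that array. The 61 genes of microtubule motors and associated proteins shifted up with 0.15 (0.0367), against -0.01 (0.768) without it and 0.0794 without ABZ replicate 1. The 41 spindle checkpoint and cell cycle genes shifted up with 0.21 (0.00127), against -0.03 (0.768). These 3 lists did not pass under quantile or cyclic loess normalization. There the medians were 0.05 (0.454) and 0.05 (0.639) for the tubulin list, 0.03 (0.832) and 0.05 (0.758) for the motors and 0.06 (0.454) and 0.04 (0.62) for the spindle list, with the test on the same side. The 44 oocyte and eggshell genes shifted up with 0.15 (0.00815), a direction that turned under cyclic loess normalization (0.969) and a call that was also lost under quantile normalization (0.996); the median was -0.08 (0.0759) without DMSO replicate 1, and the list did not pass without ABZ replicate 3 (0.121). All 33 proteasome genes had a positive fold change, and the list shifted up with a median of 0.16 (0.000753), a direction that turned under quantile and cyclic loess normalization; without DMSO replicate 1 the median was -0.02 (0.825). The 36 histone genes shifted up with 0.20 (0.00655), but not under quantile (median 0.05, 0.832) or cyclic loess normalization (median 0.04, 0.758). The histone list also did not pass without DMSO replicate 1 (median 0.05, 0.0715) or without ABZ replicate 3 (0.0511).

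Lists of dimmer or structural genes shifted down with all 6 arrays, each with an adjusted p = 0.794 with an estimated correlation. The C-type lectins, 220 genes of which 61 were positive, shifted down with a median of -0.18 (adjusted p 0.000543), a direction kept under all 3 scalings while the call was lost under cyclic loess (median -0.07, 0.0572), but the median was -0.02 without DMSO replicate 1 (0.768), where the test turned to the higher side. The 144 collagens shifted down with -0.07 (0.0484), a direction kept under all 3 scalings, but the call was lost with the arrays shifted to 1 median (0.0585). It was also lost without DMSO replicate 1 (median -0.02, 0.6), where the test turned to the higher side, and without ABZ replicate 1 (0.0545) or ABZ replicate 2 (0.0528). The 413 genes of F-box, MATH and BTB proteins shifted down with -0.05 (0.0127), a direction that turned under quantile and cyclic loess normalization. That list did not pass without DMSO replicate 1 (0.698), ABZ replicate 1 (0.052) or ABZ replicate 2 (0.0528).

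The 79 sperm genes did not pass (adjusted p 0.816). Their median of 0.10 and mean of 0.05 were positive while the test lay on the lower side, and it turned under quantile and cyclic loess normalization. Their result rested on replicate 1 of each group: without ABZ replicate 1 the list shifted down (median -0.32, 5.24e-07), without DMSO replicate 1 it shifted up (0.24, 0.00578), and with both left out it did not pass (-0.02, 0.517). Neither call held with an estimated correlation: adjusted p = 0.756 with an estimated correlation without ABZ replicate 1 and adjusted p = 0.94 with an estimated correlation without DMSO replicate 1. In the 23 major sperm protein genes of this list, ABZ replicate 1 lay above the mean of ABZ replicates 2 and 3 by a median of 2.17 and DMSO replicate 1 above its group by 1.7, on 23 of 23 genes each time. These genes are near-identical in sequence, and their probe sets are not independent of each other.

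Further lists did not pass. The 5 vitellogenins had a median of 0.05 (adjusted p 0.373), 55 embryo zygotic genes 0.00 (0.735), 98 moulting genes 0.00 (0.957) and 20 genes of apoptosis and DNA damage 0.13 (0.226). The 112 antimicrobial and infection-response genes had 0.00 (0.606) and passed with replicate 1 of both groups left out (0.02, 0.0291). The medians were 0.01 (0.865) for 47 daf-16 pathway genes, 0.08 (0.211) for 121 genes of fatty acid and lipid metabolism and 0.02 (0.394) for 76 ribosomal proteins. The 32 genes of glycolysis, trehalose and glycerol metabolism had 0.14 (0.0601) and passed without ABZ replicate 3 (0.00528), DMSO replicate 2 (0.00682) or DMSO replicate 3 (0.0281); the lipid list passed without ABZ replicate 3 (0.0324). For the embryo and daf-16 lists the means were 0.02 and 0.03 while the test lay on the lower side. Of the lists that did not pass, the oxidative stress, apoptosis, moulting, embryo, intestine, lipid, glycolysis and ribosomal lists also changed sides under quantile and cyclic loess normalization. Leaving out DMSO replicate 1, the oxidative stress (median -0.02), apoptosis (-0.04), glycolysis (-0.01) and embryo lists (-0.01) changed sides and did not pass.

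In all, 16 of the 34 lists passed, 12 up and 4 down, and 0 with an estimated correlation. When any 1 array or replicate 1 of both groups was left out, the count with an estimated correlation was also 0, so the list calls given for those settings rest on the preset correlation. Leaving out DMSO replicate 1, 5 passed, of which the cyp-35 subfamily, the unfolded protein response of the endoplasmic reticulum, muscle and neuron genes were the 4 that passed in the same direction with all arrays. No member of any list passed over all probe sets, and adjusted over the list alone 6 members were higher and 1 was lower. Without DMSO replicate 1 the count adjusted over the list alone was 6 higher and 3 lower: cyp-35C1, cyp-35A5, cyp-35A2, gst-5, irg-6 (log2 fold change 1.55) and nlp-33 (0.44) were higher, and the lysozyme gene lys-3 (-1.03), gst-29 (-0.48) and the small heat shock protein gene hsp-16.2 (-0.69) were lower. The genes irg-6, nlp-33, lys-3, gst-29 and hsp-16.2 were chosen after their values were seen.

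**Figure D3:**
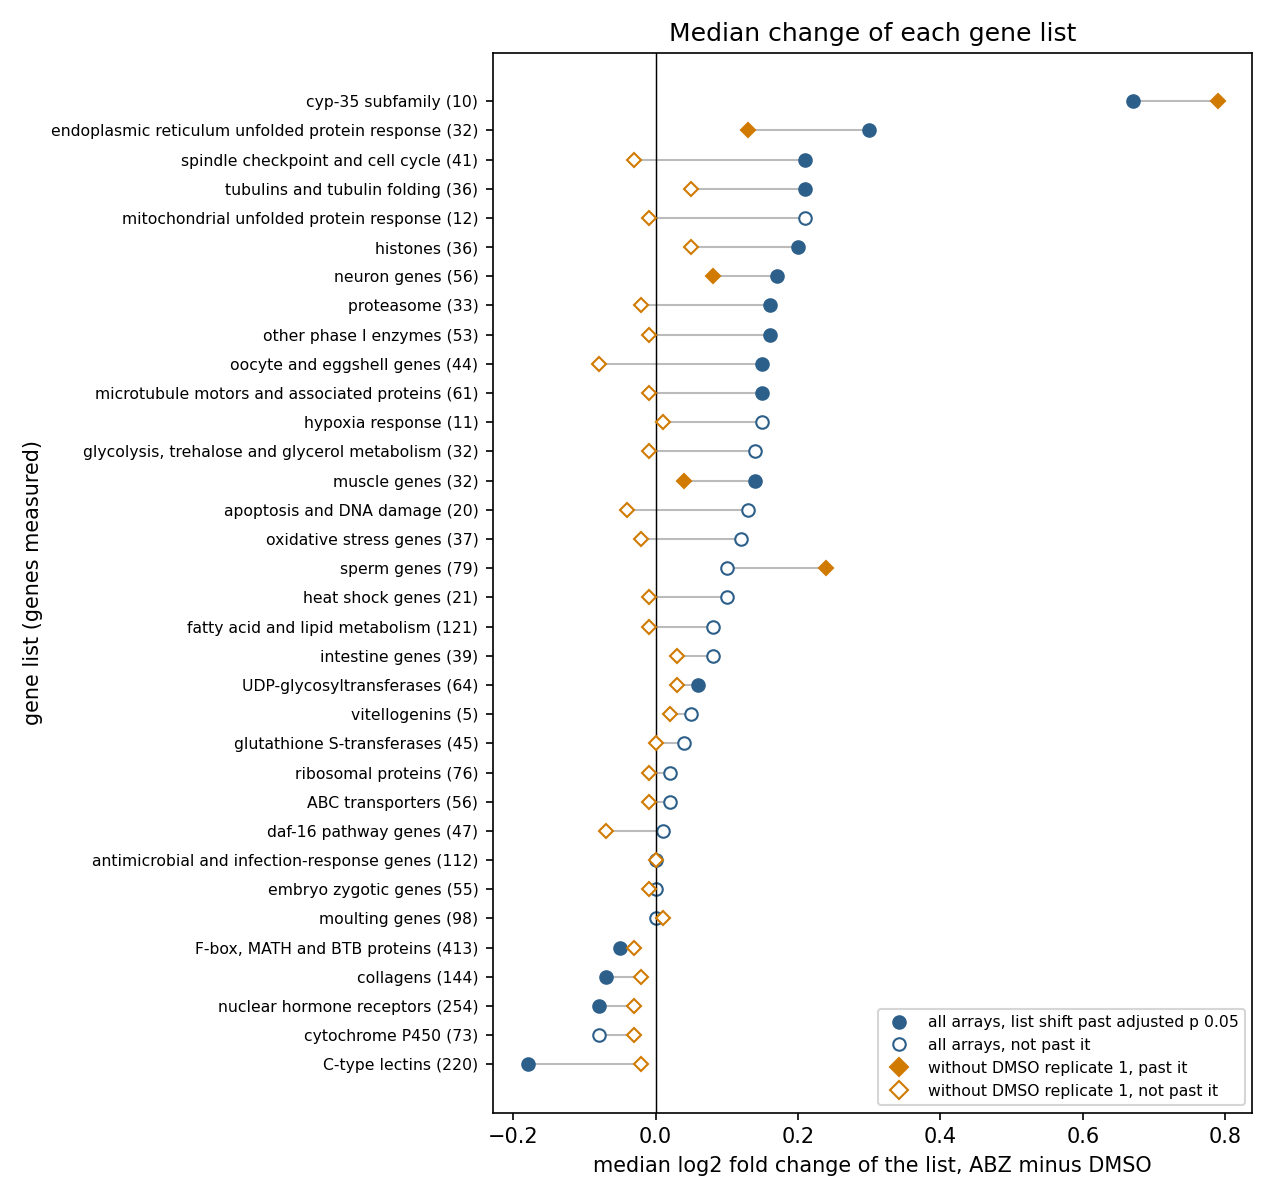
Median log2 fold change (horizontal axis, albendazole minus DMSO) of the genes of each of the 34 lists (vertical axis), with all 6 arrays (circles) and without DMSO replicate 1 (diamonds); filled symbols mark an adjusted p under 0.05. The cyp-35 subfamily has the largest medians, 0.67 with all arrays and 0.79 without DMSO replicate 1, and the other medians without that array lie between -0.08 and 0.24.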

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

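Every test in this part was chosen after the result was seen, except the counts over splits of the arrays for gene lists and for the mean of the cyp-35 subfamily. Among the Affymetrix control probe sets, which the comparison does not use, the 6 probe sets of the control transcript dap were higher with albendazole by 0.53 on the log2 scale. The 3 albendazole arrays had 8.59, 8.35 and 8.18 and the 3 DMSO arrays 7.25, 8.1 and 8.16, and without DMSO replicate 1 the difference was 0.24. The transcript was picked as the control with the largest difference. In no other control did all albendazole values lie above all DMSO values, and the other differences lay between -0.3 and 0.29. In the controls gly14 and yel002c/wbp1 all albendazole values lay below all DMSO values. Their differences were -0.14 and -0.3, and -0.05 and -0.16 without DMSO replicate 1.

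DMSO replicate 1 stood apart from the other 5 arrays, with a narrower range of signal. The bacterial and phage transcripts added to the hybridisation mix, which do not come from the worms, deviated on it by a median of -0.55, against -0.19 to 0.1 on the other arrays, and it was the lowest array on 15 of their 18 probe sets. These probe sets measure BioB, BioC, BioD and Cre and are not independent of each other. The mean of each transcript was lowest on that array, at 7.36, 8.07, 10.25 and 12.36. The values had been through RMA with the worm probe sets, so they are not fully separate from the worm signal. Within this limit they argue against a different state of the worms in that culture as the whole cause. A fault of that array's hybridisation, staining or scan may account for the difference. The mean difference between 3′ and 5′ probe sets of 4 worm control transcripts was 0.71, inside the range of 0.61 to 0.76 of the other arrays. This gives no sign of degraded RNA but cannot exclude it, since the narrowed range of that array can alter such differences. A smaller difference of the worms beneath an array fault stays open, since the raw scans were not used here.

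Of the 16 gene lists that passed with all 6 arrays, 4 also passed in the same direction without DMSO replicate 1, whereas 12 to 15 did without any other single array; for 10 of the 12 that were lost, among them the tubulins, the spindle checkpoint and the proteasome, the call was also lost with the trend with signal removed from all 6 arrays, and the narrowed signal range of DMSO replicate 1 is a candidate explanation; of these, the C-type lectins still passed under quantile normalization (0.0278). The other 2, the UDP-glycosyltransferases (adjusted p 0.00495) and collagens (2.57e-05), passed in the same direction with the trend removed, which argues against the narrowed range as their whole cause; the collagen shift still rests on that array, since the test turned to the higher side without it (0.6). The 4 kept lists were picked because they passed without the array, so that pass is no separate test of it. With the trend removed from all 6 arrays, 3 of them passed in the same direction. These were the cyp-35 subfamily, the unfolded protein response of the endoplasmic reticulum (0.0483) and the neuron genes (0.018). Their pass with all 6 arrays argues against the narrowed signal range as their whole cause. They also passed with DMSO replicate 1 left out as well. That is again no separate test, since they were picked for a pass without it. The medians of the endoplasmic reticulum and neuron lists still went from 0.30 to 0.13 and from 0.17 to 0.08 without DMSO replicate 1. Muscle genes did not pass with the trend removed (0.683), nor with that array also left out (0.102). With an estimated correlation no list passed with or without DMSO replicate 1 (smallest adjusted p 0.794 and 0.94), so correlated genes stay an open explanation of all these lists, and so does the exposure itself.

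The major sperm protein genes were higher in replicate 1 of both groups, by a median of 2.17 in ABZ replicate 1 and 1.7 in DMSO replicate 1. A fault of these near-identical probe sets alone was tested on the 56 other sperm genes, whose median difference in ABZ replicate 1 was 0.3, with 38 of 56 positive, and in DMSO replicate 1 0.33, with 44 positive; the first lies between what a probe set fault and a rise of all sperm genes would give, and the second comes from the array whose dim probe sets lay higher by up to 0.28. An earlier stage of the replicate 1 cultures was tested on the oocyte and eggshell genes, with a median difference of -0.11 in ABZ replicate 1 and -0.82 in DMSO replicate 1, and on the vitellogenins, with -0.03 and -0.06. The value of -0.82 decides nothing, since DMSO replicate 1 has the narrowed range and its spindle and cell cycle genes, also bright, differed by -0.67, so the explanations cannot be told apart with 1 such array in each group. Males or another source of sperm transcripts in these cultures were not tested.

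The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For probe sets that pass the threshold the real value was 0 and the highest other 3. Every split must reach 0, so the 10 of 10 splits that gave as many decide nothing. At an unadjusted p under 0.05 there were 420 probe sets against a highest other of 579, with 2 of 10 splits as large. For gene lists the real count was 16 and the highest other 19, with 8 of 10 splits as large. The mean change of the cyp-35 subfamily was 1.13 against a highest other of 0.77, with 1 of 10 splits as large, the real one.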

How the results depend on the processing

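Cyclic loess normalization, the gene-by-gene weights, the removed signal trend, both settings that combine it or the robust fit with DMSO replicate 1 left out, the estimated correlation with arrays left out, and the setting without replicate 1 of both groups were chosen after the data were seen. The cause was not tested for any change given here, except that settings without arrays hold fewer samples. Of the fold changes of named genes that were called under any setting, 0 reversed; uncalled ones changed sign for tba-1 (7 settings), tbb-1 (5), cyp-35A4 and tba-2 (3 each), mec-7 (2) and cyp-35A3, cyp-35B2, cyp-35B3 and cyp-35D1 (1 each). The log2 fold change of cyp-35C1 ranged from 2.94 to 3.59 and that of cyp-35A5 from 2.64 to 3.74, and the calls of cyp-35C1, cyp-35A5 and cyp-35A2 over the cyp-35 list alone held in every setting. The adjusted p of cyp-35A5 over the P450 list was 0.0588 with the replicate number as a block. Over the list alone, all 3 ugt calls were lost under quantile normalization (0.0711 each), with the intensity trend and robust settings (0.0656 each), with the block (ugt-16 0.152, ugt-5 and ugt-53 0.154), under cyclic loess normalization (ugt-16 and ugt-5 0.116, ugt-53 0.0783) and with replicate 1 of both groups left out (0.092 each). Detection calls were not used here, so what signal over background limits is not given.

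No probe set passed at an adjusted p under 0.01 or with a change of at least 2-fold, and no gene when 1 probe set per gene was counted. Array weights gave 25 higher and 3 lower probe sets, 4662 at an unadjusted p under 0.05, 5 lists, 31 name classes, and 53 higher and 26 lower list members adjusted over the list alone. The gene-by-gene weights gave 5 higher probe sets, 2232 at an unadjusted p under 0.05, 5 lists, 34 classes, and 21 higher and 5 lower members. Without DMSO replicate 1 and with the intensity trend and robust settings, 2 probe sets were higher and 1389 lay under 0.05. With replicate 1 of both groups left out, 923 lay under 0.05, 5 lists and 22 classes passed, and 2 members were lower. The labels state no pairing; each array correlated best, in its deviations from its group mean, with the array of its own number, at 0.125, 0.264 and 0.066. With the replicate number as a block, 259 probe sets lay under 0.05, 16 lists passed and 0 members were lower. With the intensity trend and robust settings 0 members were lower.

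Quantile normalization left 6 lists, 4 classes, and 3 higher and 0 lower members; cyclic loess left 5 lists, 4 classes, and 3 higher and 0 lower members. Without the dimmest probe sets 6 lists and 29 classes passed, with fewer genes tested. With the signal trend removed 5 lists and 8 classes passed, and with DMSO replicate 1 also left out 5 lists and 15 classes. With an estimated correlation 0 lists and 0 classes passed, and fry gave 0 lists in the directional and 0 in the mixed test; the smallest adjusted p with an estimated correlation was 0.794. With each array, or replicate 1 of both groups, also left out, 0 lists passed, at smallest adjusted p values from 0.756 to 0.997. With single arrays left out, the probe sets under 0.05 ranged from 105 (without ABZ replicate 1) to 1294 (without DMSO replicate 1), with 0 higher and 0 lower called each time. The lists ranged from 5 (without DMSO replicate 1) to 18, the classes from 35 (without DMSO replicate 1) to 76, the higher members from 3 (without ABZ replicate 1) to 8 and the lower members from 0 to 3.

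The list tests reversed as follows, given as the median log2 fold change; the side is that of the test against all other genes, which can differ from the sign of the median. With single arrays left out the C-type lectins ranged from -0.25 to -0.02, collagens from -0.15 to -0.02, motors from -0.01 to 0.30, oocyte genes from -0.08 to 0.35, the proteasome from -0.02 to 0.29 and sperm genes from -0.32 to 0.28; all 6 reversed without DMSO replicate 1, at -0.02, -0.02, -0.01, -0.08, -0.02 and 0.24. Removing the trend changes the test and not the fold changes, so the medians are by construction those without it: with DMSO replicate 1 also left out these 6 lists were reversed at -0.02, -0.02, -0.01, -0.08, -0.02 and 0.24, F-box genes were at -0.03, nuclear hormone receptors at -0.03 and the spindle list at -0.03. With the trend removed and all arrays, F-box genes were at -0.05, nuclear hormone receptors at -0.08, oocyte genes at 0.15 and the proteasome at 0.16. Under quantile normalization F-box genes were at 0.01, nuclear hormone receptors at -0.01 and the proteasome at 0.00. Under cyclic loess they were at 0.03, 0.02 and 0.00, and oocyte genes at 0.00. With array weights collagens were at 0.00; with gene-by-gene weights collagens were at 0.00, nuclear hormone receptors at -0.02 and oocyte genes at -0.03. With replicate 1 of both groups left out F-box genes were at -0.01, collagens at 0.00, motors at -0.02, nuclear hormone receptors at 0.00 and oocyte genes at -0.03. Of all list results under other settings, 456 kept the direction of the test and its side of the threshold, 129 kept the direction but were no longer past the threshold and 10 newly passed. The direction turned in 35 that were past the threshold in 1 of the compared settings or both, and in 84 that were past it in neither. The planned pseudocount alternative did not apply to log2 values, and Fisher's exact test of name classes could not be run under any setting without called genes.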

Other observations

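All tests in this part were chosen after the data were seen. Of 233 classes of genes that share a name stem, 63 shifted in camera's test with all arrays, 35 without DMSO replicate 1 and 27 in the same direction in both. After the signal trend was also removed 9 of these still passed, and 0 passed with an estimated correlation (adjusted p = 0.756 with an estimated correlation for each of the 9). The innexins (inx), which form gap junctions, shifted up under all 3 scalings and without each single array: the median of 21 genes was 0.32 with all arrays (adjusted p 4e-05), 0.24 under cyclic loess (0.00133) and 0.09 without DMSO replicate 1 (0.00217). Subunits of the vacuolar proton pump (vha, 18 genes) had a median of 0.24, and 0.15 without DMSO replicate 1 (0.000526). They pointed up under all 3 scalings and did not pass under quantile (0.163) or cyclic loess normalization (0.329).

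Neuropeptide-like protein genes (nlp, 58 genes) had a median of 0.14, and 0.08 without DMSO replicate 1 (0.000526). Their direction held under all 3 scalings, and they did not pass without ABZ replicate 2 (0.175), without DMSO replicate 3 (0.265), or under quantile (0.163) or cyclic loess normalization (0.231). The infection-response class irg (8 genes) had 0.35, and 0.42 without DMSO replicate 1 (0.00556), in the same direction under all 3 scalings; it did not pass without DMSO replicate 2 (0.0873), or under quantile (0.214) or cyclic loess normalization (0.376). The classes unc and sup, named for mutant phenotypes, had medians of 0.18 and 0.30, and 0.06 and 0.13 without DMSO replicate 1; unc did not pass with replicate 1 of both groups left out (median 0.02, 0.16). The chemoreceptor classes srh, srw and sri, dim on average, had -0.10, -0.11 and -0.16, and -0.07, -0.07 and -0.08 without DMSO replicate 1. These 5 classes kept the side of their test under all 3 scalings but did not pass under quantile or cyclic loess normalization, and the medians of srh and srw were 0.02 under cyclic loess.

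Among the 3 albendazole arrays, ABZ replicate 2 held the highest value of 9 of the 10 cyp-35 genes, and the median difference of the 10 genes from the mean of the other albendazole arrays was 1.03. In the same comparison, 20 of 34 other genes higher at an unadjusted p under 0.01 were highest in ABZ replicate 2, as were 29.5% of all genes.

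A hypothesis was that genes higher with albendazole lie next to each other in the genome more often than chance gives. Among 37 genes higher at an unadjusted p under 0.01, in the gene order of the WBcel235 assembly, 3 adjacent pairs were found; random sets of the same size from 17078 genes had a median of 0 and at most 3 (permutation p 2e-04, 10000 sets). The pairs were F35E12.9 with F35E12.10, F35E12.10 with cld-9, and F20G2.5 with F53C11.1, of which the first 2 form 1 chain of 3 genes. With the probe sets left out whose type allows a match to related transcripts, 30 genes and 1 pair remained (permutation p 0.0545). This step also left fewer genes, and F35E12.9 and cld-9 are measured by probe sets that are not of that type. Probe overlap between neighbours was not examined, so whether shared probes account for the excess of 3 pairs stays open. F35E12.9 and cld-9 were already known to be among the genes with the smallest p values when the test was chosen, and none of the 37 genes passed over all probe sets.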
